A study of Homo sapiens with 8 samples.

How the data were processed

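RNA from 8 tumours was measured on Agilent human arrays with 1 colour (Cy3), 1 array per tumour, 4 from the vehicle group and 4 from the PD325901 group. Groups and replicate numbers were taken from the sample titles. Per the file headers, the deposited scanner files hold background-subtracted processed signals, an intensity on a linear scale for each spot, made with Feature Extraction 10.7.3.1. The submitters' processing notes name Agilent Feature Extraction 9.1. The second deposited table, the series matrix, holds log2 values of the same arrays. Set against the scanner values, its 41000 probe rows correlated at 0.999 or above with the log2 processed signal after 75th percentile scaling and centring of each probe on its median over the 8 arrays, in the same direction, and 93 further rows are controls. The medians of its columns were 0.0706, -0.00588, 0.206 and 0.0346 for vehicle replicates 1 to 4 and -0.0796, -0.112, -0.0681 and 0.0238 for PD325901 replicates 1 to 4. Its scale, centring and direction were therefore settled from the values, and the labels do not state them. The table served as an alternative only.

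Each array held 45015 spots, of which 1639 control spots were left out. The remaining 43376 spots represent 41000 probes. The log2 of the processed signal minus the log2 of the array's 75th percentile was used as the value of a spot. Spots flagged as non-uniformity or population outliers were set missing on that array (0.127% to 1.01% of spots), and 2 saturated spots over all arrays were kept. Spots of one probe were averaged. A probe was kept if it had at least 3 values per group and was well above background on every unflagged array of at least 1 group, which left 25050 probes. The files give an accession per probe and no gene name, so genes were named by matching accessions, without versions, to the RefSeq gene table of GRCh38.p14. This named 24794 probes, each with 1 symbol, and left 16206 unnamed, and 17413 of the kept probes were named. The array design was built on NCBI36, so no coordinates are given. A gene was represented by its kept probe with the highest mean, which gave 12183 genes. Of the changed genes, 506 had other kept probes, and in 67 of these at least 1 of them had a log2 fold change of the opposite sign.

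The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, PD325901 minus vehicle), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean against the dimmer group's mean, where each dimmer array counts at the higher of its own value and the lowest value among probes well above background on that array. Without counts there is no depth to state, and the number of arrays limits the precision.

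The 26 gene lists, the processing alternatives and the rule for named genes were fixed before the data were examined. The lists cover ERK feedback, ERK-responsive transcription factors, DNA replication, mitosis, quiescence, apoptosis, receptors, cytokines, invasion, epithelial and mesenchymal state, hypoxia, glycolysis, cholesterol and fatty acid synthesis, lysosome, interferon, MYC targets, ATF4 and unfolded protein response, heat shock, Wnt and YAP targets, and markers of 7 other cell types. Lists with at least 5 measured members, 23 of them, were tested with camera at its preset inter-gene correlation of 0.01, leaving out 289 genes with a missing value, with an estimated correlation and fry as alternatives. No list passed with the estimated correlation. A list score per tumour, the mean over members of the log2 value minus the gene's mean over all tumours, was compared with a two-sided exact permutation test over the 70 assignments. Genes are named if they are among the 8 largest rises or the 8 largest falls that passed the test, did not overlap between groups and carry a gene symbol that is not a clone, locus or open-reading-frame name, or if they are among the 4 largest changes past the threshold of the first 4 lists or the 2 largest of the other lists (the 2 smallest p where none passed). MAP2K1, MAP2K2 and MAPK3 are named for context. A further 3 genes that the fixed rule names are left out of the text.

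Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, cyclic loess, no filter on detection, a filter on all 8 arrays, flagged spots kept, the mean of the kept probes of a gene, the series matrix values, the replicate number as a block, eBayes with trend and robust, array quality weights, and leaving out each tumour in turn. The median signal and the median background were used for normexp, since the files hold no mean signal column. Its offset of 50 is added to each signal, which by itself shrinks the folds of dim probes. The slide could not be fitted as a block because each slide held 1 group. On data simulated for this comparison from the means and spreads of 11894 genes, with 200 genes changed, 24% of changes of 0.5 log2 units, 80% of 1, 96% of 2 and 100% of 4 were recovered, each from 50 genes, and 6.25% of the calls were false. In a second simulation of the same genes a list shifted by 1 log2 unit was called and no other. Both simulations drew the genes independently, so they do not test the preset correlation. The shifted list, mitosis and G2/M, had an estimated correlation of 0.627 in the tumours.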

Results

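Gene expression was measured in tumours formed by MIA/luc cells, described by the submitters as a pancreatic cancer cell line, in NOD-SCID mice, a strain that lacks functional T and B lymphocytes. The comparison addresses which genes are regulated by treatment with a MEK inhibitor. PD325901 blocks MEK1 and MEK2, the kinases that activate the ERK kinases. The 8 tumours form 2 groups of 4, treated with PD325901 or with vehicle alone, and each was hybridised to one 1-colour Agilent array of human probes. Dose, treatment time and site of the tumour are not given in the sources used here. Between 61.0% and 69.1% of the probe spots on an array were well above background, and the 75th percentile of the processed signal lay between 746 and 1456 units. The labels give 1 tumour per array without stating that each came from a separate mouse, so p-values measure only the spread between these samples. All 4 vehicle arrays lay on 1 slide and all 4 PD325901 arrays on another, so slide and treatment cannot be told apart.

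In tumours given PD325901, 8 of 12 measured ERK feedback regulators and 15 of 21 measured ERK-responsive transcription factors passed as lower, and no member of either list passed as higher. The steepest fall was in SPRY4, an inhibitor of receptor tyrosine kinase signalling, whose log2 signal relative to the array's 75th percentile went from 0.46 ± 0.15 (SD, n = 4) under vehicle to -4.18 ± 0.19 (SD, n = 4) under PD325901, 25.0-fold lower (limma, adjusted p = 5.59e-07). The cytokine gene CSF3 was at least 10.9-fold lower, since its probe was not well above background on any PD325901 array. TOX2, a transcription factor gene, was 12.6-fold lower (adjusted p = 5.50e-06) and HSD3B1, a steroid dehydrogenase gene, 15.1-fold lower (adjusted p = 0.0234), its probe being well above background on 2 of the 4 PD325901 arrays. CFHR3, a gene of the complement system, was at least 4.63-fold lower. These bounds hold for the background-subtracted signal: with normexp background correction the log2 fold change was -2.16 for CSF3 and -1.66 for CFHR3, and it was -3.60 for SPRY4 and -2.58 for HSD3B1. The fold of HSD3B1 also depended on vehicle replicates 2 and 3 (log2 fold change -3.25 without the former and -4.78 without the latter), and its call was lost in 5 of 21 alternatives (adjusted p from 0.00201 to 0.0890).

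The steepest rise among genes whose groups did not overlap was in LY6D, a surface protein of stratified epithelium, from -3.44 ± 1.80 to 2.02 ± 0.68 (SD, n = 4 per group), 44.0-fold (limma, adjusted p = 0.00343). The metalloproteinase genes MMP13 and MMP10 were 25.6-fold and 12.3-fold higher, the probe of MMP13 being well above background on 2 of the 4 vehicle arrays. CSF1R, the receptor for colony stimulating factor 1, rose from -3.55 ± 0.46 to 0.02 ± 0.17 (SD, n = 4 per group), 11.9-fold (adjusted p = 9.68e-05). The oxytocin receptor gene OXTR was 10.5-fold higher on its brightest probe, well above background on 2 of the 4 vehicle arrays, with a log2 fold change of 0.83 on its second kept probe. The probes of a further 3 genes were not well above background on any vehicle array, so their rises have only a lower bound: at least 8.20-fold for the keratin gene KRT6A, at least 7.998-fold for the endothelin gene EDN2 and at least 5.20-fold for the adhesion gene NECTIN4. With normexp these 3 genes no longer passed, at log2 fold changes of 1.33, 1.18 and 0.69, which lie below their bounds, nor did OXTR, at 1.30. The offset that normexp adds shrinks the folds of such dim probes by itself, and its share in these losses was not tested. Over all alternatives the adjusted p ranged from 0.00394 to 0.197 for KRT6A, from 0.000306 to 0.149 for EDN2, from 0.000109 to 0.315 for NECTIN4 and from 0.000150 to 0.0633 for OXTR. The call of KRT6A was lost in 2 of 21 alternatives, and its log2 fold change was 3.61 without PD325901 replicate 2. With normexp the log2 fold change was 3.82 for LY6D, 3.19 for MMP13, 2.77 for MMP10 and 2.15 for CSF1R. It was 6.35 for LY6D without vehicle replicate 3, and 5.39 for MMP13 and 4.23 for MMP10 without vehicle replicate 4. The call of MMP10 was lost in 1 of 22 alternatives (adjusted p from 0.000454 to 0.0532).

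Over all 12183 genes tested, 1890 (15.5%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg). Of these, 888 were higher and 1002 lower under PD325901, and 464 differed at least 2-fold, 185 higher and 279 lower. At the level of probes, named or not, 3152 of 25050 changed. The values of the 2 groups did not overlap for 2916 genes, 23.9% of those tested against the 2.86% that chance gives. Correlations between arrays were 0.971 to 0.992 within the vehicle group, 0.984 to 0.993 within the PD325901 group and 0.957 to 0.978 between groups, and the first principal component (46.9% of the variance) separated the groups. The split into rises and falls depended on the scaling: 1789 higher and 636 lower with median scaling, which moves the median log2 fold change of all genes from 0.01 to 0.16, and 1046 higher and 717 lower with quantile normalization. The number of changed genes was 1152 with normexp, 962 without PD325901 replicate 3, 1093 without PD325901 replicate 1, 1209 without PD325901 replicate 2 and 1229 without vehicle replicate 2. Pancreatic acinar transcripts were high in PD325901 replicates 3 and 4, and without both, an alternative chosen after seeing the data, 642 genes changed. Without vehicle replicates 1 and 3, also an alternative chosen after, 1295 changed. These pairs are not matched: on the second principal component the vehicle pair lay at -25.0 and 38.9, the PD325901 pair at 1.94 and -0.51. Without PD325901 replicate 4 alone, whose acinar score was the highest, 1308 genes changed. The counts therefore do not tell whether acinar content carries the calls. Of the 53 named genes past the threshold, 23 passed under each alternative that tested them, and with normexp 21 had a fold over 1.5 times off.

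Most measured genes of the 2 ERK-linked lists fell. Of 12 measured ERK feedback regulators, proteins made in response to ERK that dampen the pathway, 8 fell, none rose and 4 did not pass (11 fell when adjusted over the list alone). Besides SPRY4 these include DUSP6, the ERK phosphatase, at least 6.72-fold lower because no PD325901 array held it well above background, SPRY1, 5.83-fold lower, and SPRY2, 4.86-fold lower. Of 21 measured ERK-responsive transcription factors, 15 fell, none rose and 6 did not pass (17 fell when adjusted over the list alone). EGR1, an immediate early gene, went from 3.83 ± 0.44 to 0.31 ± 0.54 (SD, n = 4 per group), 11.5-fold lower. EGR2 was 10.6-fold lower with 1 PD325901 array well above background, EGR3 at least 3.32-fold lower with none, and EGR4 6.74-fold lower. With normexp the log2 fold changes of DUSP6, EGR2 and EGR3 were -1.75, -2.04 and -1.72, those of DUSP6 and EGR3 short of the bounds. The median log2 fold change was -1.28 for the feedback regulators and -1.26 for the transcription factors, also with DUSP6 and EGR3 at their bounds. Both lists passed camera with its preset correlation (adjusted p = 2.26e-09 and 2.98e-12). With an estimated correlation they did not (adjusted p = 0.0911 and 0.104), and with fry they did (adjusted p = 3.41e-05 and 0.000304). The list score of every PD325901 tumour lay below that of every vehicle tumour for both lists, with a difference of -1.67 and of -1.51 log2 units (two-sided exact permutation p = 0.0286 each, the smallest that 70 assignments allow, and 0.0821 after adjustment over the 23 lists).

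**Figure D1:**
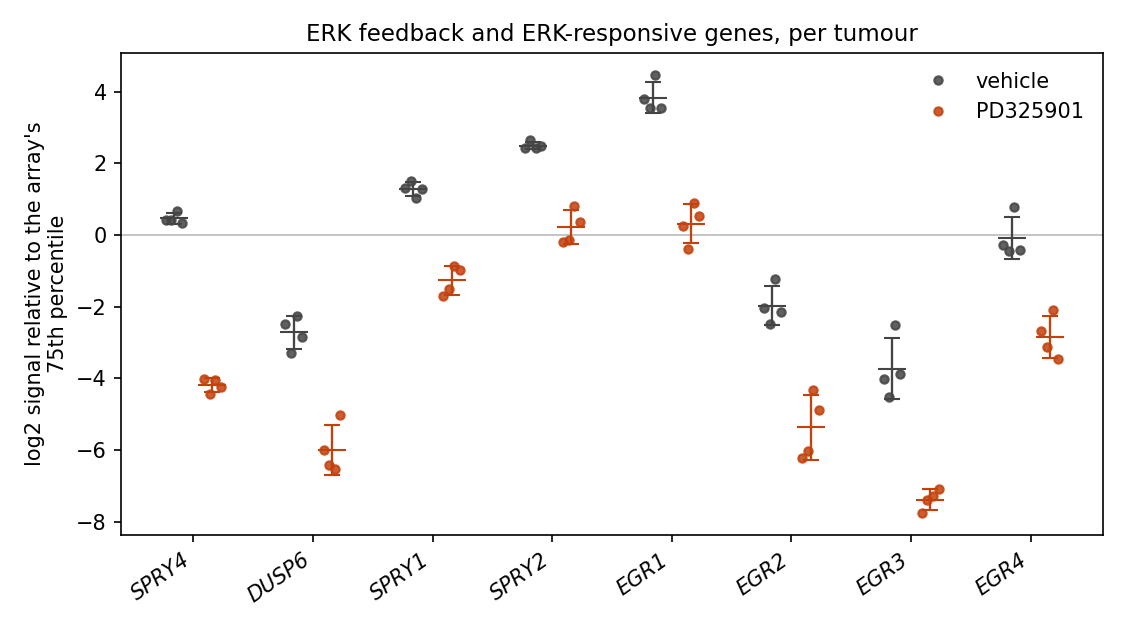
Log2 signal relative to the 75th percentile of each array for 4 ERK feedback regulators and 4 ERK-responsive transcription factors. Points are tumours, horizontal bars are group means and error bars are 1 SD (n = 4 per group). In each of the 8 genes the PD325901 tumours lie below all vehicle tumours, with SPRY4 at -4.18 against 0.46 and EGR1 at 0.31 against 3.83.

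Median fold changes of the 2 cell cycle lists were smaller. Of 33 measured genes of mitosis and G2/M, 5 fell, none rose and 28 did not pass (7 fell when adjusted over the list alone), with a median log2 fold change of -0.25. The falls were in the spindle checkpoint kinase genes TTK (log2 fold change -0.57) and BUB1B (-0.48), in PTTG1, the securin gene (-0.49), in TOP2A, the topoisomerase of chromosome segregation (-0.43), and in DLGAP5, a spindle gene chosen after its values were seen (-0.41). The list passed camera with the preset correlation (adjusted p = 0.000417) and not with an estimated correlation (adjusted p = 0.725) or with normexp (adjusted p = 0.101, the highest of the 22 alternatives, which start at 9.15e-06), and its score differed by -0.26 with overlapping groups (exact permutation p = 0.0857). The difference was -0.16 with PD325901 replicate 4 left out, whose score was the lowest (-0.42) and whose fibroblast (0.67), macrophage (0.48) and acinar (3.91) scores were the highest, while PD325901 replicates 2 and 3 (0.04 and 0.02) lay above vehicle replicate 3 (-0.02). Of 33 measured genes of DNA replication and G1/S, 1 rose, 1 fell and 31 did not pass (none when adjusted over the list alone; camera adjusted p = 0.278). The one that fell was RRM2, a subunit of ribonucleotide reductase (log2 fold change -0.69, adjusted p = 0.0473), and the one that rose was CCNE1, the cyclin E1 gene (0.35, adjusted p = 0.0223). Leaving out single tumours ended the call of RRM2 in 7 of 8 cases, of TTK in 7 and of TOP2A in 8. Of 22 alternatives PTTG1 passed in 12, BUB1B in 16 and CCNE1 in 15, with adjusted p up to 0.16005, 0.149 and 0.111. Of 19 measured CDK inhibitors and quiescence genes, 6 rose, 1 fell and 12 did not pass (7 rose and 1 fell when adjusted over the list alone). CDKN2D, a CDK inhibitor chosen after its values were seen, was the one that fell (-0.96). GAS1, a growth arrest gene, was 2.79-fold higher and the antiproliferative gene BTG2 2.20-fold higher. This list passed camera with the preset correlation (adjusted p = 0.0430) and not with an estimated correlation (adjusted p = 0.334), and it passed in 10 of 22 alternatives (adjusted p from 0.00992 to 0.117).

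Each of the next 6 lists held genes that rose and genes that fell, and none passed camera, which compares a list with all other genes. In 4 of them the list scores of the groups did not overlap (exact permutation p = 0.0286 each, adjusted 0.0821), with a difference of -0.23 for receptor tyrosine kinases and ligands, -0.51 for cytokines and chemokines, 0.52 for invasion and 0.23 for Wnt and YAP targets. With fry, which tests whether members move one way on balance, the adjusted p was 0.000772 for Wnt and YAP targets (up), 0.0133 for epithelial and mesenchymal state (down), 0.0166 for the BCL2 family (down), 0.0674 for cytokines, 0.180 for receptors and 0.967 for invasion. The lists of epithelial and mesenchymal state and of the BCL2 family each mix genes of opposite function. A direction of these 2 lists is therefore not a direction of apoptosis or of either cell state. The score of the BCL2 family differed by -0.04 (exact permutation p = 0.2) and by 0.11 with median scaling (p = 0.0286). That of epithelial and mesenchymal state differed by -0.06 (exact permutation p = 0.171). It turned positive with quantile normalization (0.058), median scaling (0.092) and cyclic loess (0.031). Wnt and YAP targets passed camera in 1 of 22 alternatives (adjusted p from 0.0257 to 0.231) and the other 5 lists in none. Among 20 measured BCL2 family and apoptosis genes, 2 rose and 3 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.450). The proapoptotic gene BIK was 3.29-fold higher and the proapoptotic gene PMAIP1 2.41-fold lower. Among 24 measured receptor tyrosine kinases and ligands, 4 rose and 7 fell (5 and 9 when adjusted over the list alone; adjusted p = 0.328). EPHA2, an ephrin receptor, was 3.29-fold lower, and PDGFRB, a platelet-derived growth factor receptor, was at least 1.57-fold higher, with a log2 fold change of -0.27 under normexp (adjusted p = 0.695, the highest of a range that starts at 0.000244). Among 13 measured cytokines and chemokines, 2 rose and 3 fell (3 and 4 when adjusted over the list alone; adjusted p = 0.526). Beside CSF3, LIF was 5.66-fold lower (adjusted p = 9.68e-05), while the median member had a log2 fold change of 0.05 and camera's direction was down. Among 17 measured genes of invasion and the plasminogen system, 2 rose, MMP13 and MMP10, and 3 fell (3 and 3 when adjusted over the list alone; adjusted p = 0.830). The median member had a log2 fold change of 0.07, against 4.68 for MMP13 and 3.62 for MMP10, so the score difference does not describe most members. Among 15 measured genes of epithelial and mesenchymal state, 3 rose and 6 fell (3 and 6 when adjusted over the list alone; adjusted p = 0.526). SNAI1 was 2.89-fold higher and TWIST1, likewise a mesenchymal transcription factor, 2.09-fold lower. Among 10 measured Wnt and YAP target genes, 4 rose and 1 fell (5 and 3 when adjusted over the list alone; adjusted p = 0.110). AXIN2, a feedback gene of the Wnt pathway, was 2.71-fold higher and CCN2, a YAP target, 2.91-fold lower. The calls of SNAI1, TWIST1 and AXIN2 were lost with normexp, that of TWIST1 also without PD325901 replicate 1, and over all alternatives their adjusted p ranged from 0.00328 to 0.0572, from 0.00982 to 0.0708 and from 0.000139 to 0.337. The call of CCN2 was kept in 11 of 21 alternatives (adjusted p from 0.00211 to 0.0762). Members of these 6 lists that passed and are named after their values were seen are BCL2L11, higher, and MCL1 and XIAP, lower, DDR1, FGFR3 and MET, higher, and DDR2, EREG, FGFR1, HBEGF, IRS1 and IRS2, lower, CXCL5 and TGFB1, higher, and CXCL8, lower, S100A4 and TIMP1, lower, DSP and JUP, higher, and CLDN4, ESRP1, KRT8, KRT18 and KRT19, lower, and AJUBA, AMOTL2 and ZNRF3, higher.

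Of 27 measured lysosome and autophagy genes, 6 rose, none fell and 21 did not pass, over all genes and over the list alone. TFEB, the transcription factor that controls lysosome genes, was 3.43-fold higher, from -0.81 ± 0.28 to 0.97 ± 0.27 (SD, n = 4 per group; limma, adjusted p = 0.000590), and SQSTM1, an autophagy receptor, 1.43-fold higher. The list passed camera with the preset correlation (adjusted p = 0.00259), not with an estimated correlation (adjusted p = 0.0911), and its score was 0.27 higher (exact permutation p = 0.0286). Its call was lost in 1 of 22 alternatives (adjusted p from 4.11e-05 to 0.0583). Among 23 measured genes of cholesterol and fatty acid synthesis, 3 fell and none rose (also 3 when adjusted over the list alone; camera adjusted p = 0.0610). Cholesterol and fatty acid synthesis passed in 4 of 22 alternatives (adjusted p from 0.00492 to 0.373). The sterol sensor gene INSIG1 was 1.86-fold lower (adjusted p = 0.0436). Among 19 measured hypoxia genes, 1 rose and 4 fell (1 and 5 when adjusted over the list alone; camera adjusted p = 0.117), a list that passed in 4 of 22 alternatives (adjusted p from 0.0162 to 0.938). The collagen crosslinking gene LOX was 3.90-fold higher and the glucose transporter gene SLC2A3 3.42-fold lower. The call of LOX was lost with normexp (adjusted p = 0.163, the highest of a range that starts at 0.000772), and that of INSIG1 in 12 of 22 alternatives (adjusted p from 0.00884 to 0.275). Members of these lists that passed and are named after their values were seen are SREBF1, lower, and ANGPTL4, DDIT4 and MXI1, lower.

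Other lists held few changed members, and none passed camera. None of 22 measured glycolysis genes passed, over all genes or over the list alone (limma; 3 had an unadjusted p under 0.05; camera adjusted p = 0.830), ALDOC having a log2 fold change of 0.76 (adjusted p = 0.0590) and ALDOA of -0.53 (adjusted p = 0.108). ALDOC passed in 4 of 22 alternatives (adjusted p from 0.0214 to 0.209). Of 23 interferon response and antigen presentation genes 1 fell, OASL (-0.72, adjusted p = 0.0327), and none when adjusted over the list alone (camera adjusted p = 0.845), with a median of 0.08 and a camera direction of down. Of 23 MYC targets and ribosome biogenesis genes 1 fell, PA2G4 (-0.35, adjusted p = 0.0252), and none when adjusted over the list alone (camera adjusted p = 0.273). Of 19 ATF4 and unfolded protein response genes 1 rose, SESN2 (0.45), and 1 fell, TRIB3 (-0.58), likewise over the list alone (camera adjusted p = 0.596). Of 13 heat shock genes 1 rose, HSPB1 (0.51), likewise over the list alone (camera adjusted p = 0.628). Of 22 alternatives, OASL and SESN2 passed in 12, PA2G4 and TRIB3 in 11 and HSPB1 in 13, with adjusted p up to 0.123, 0.130, 0.337, 0.219 and 0.0955. In 14 of the 35 possible splits of the 8 tumours into 4 and 4, the real one included, camera with the preset correlation called at least 6 lists, the number it called in the real one.

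**Figure D2:**
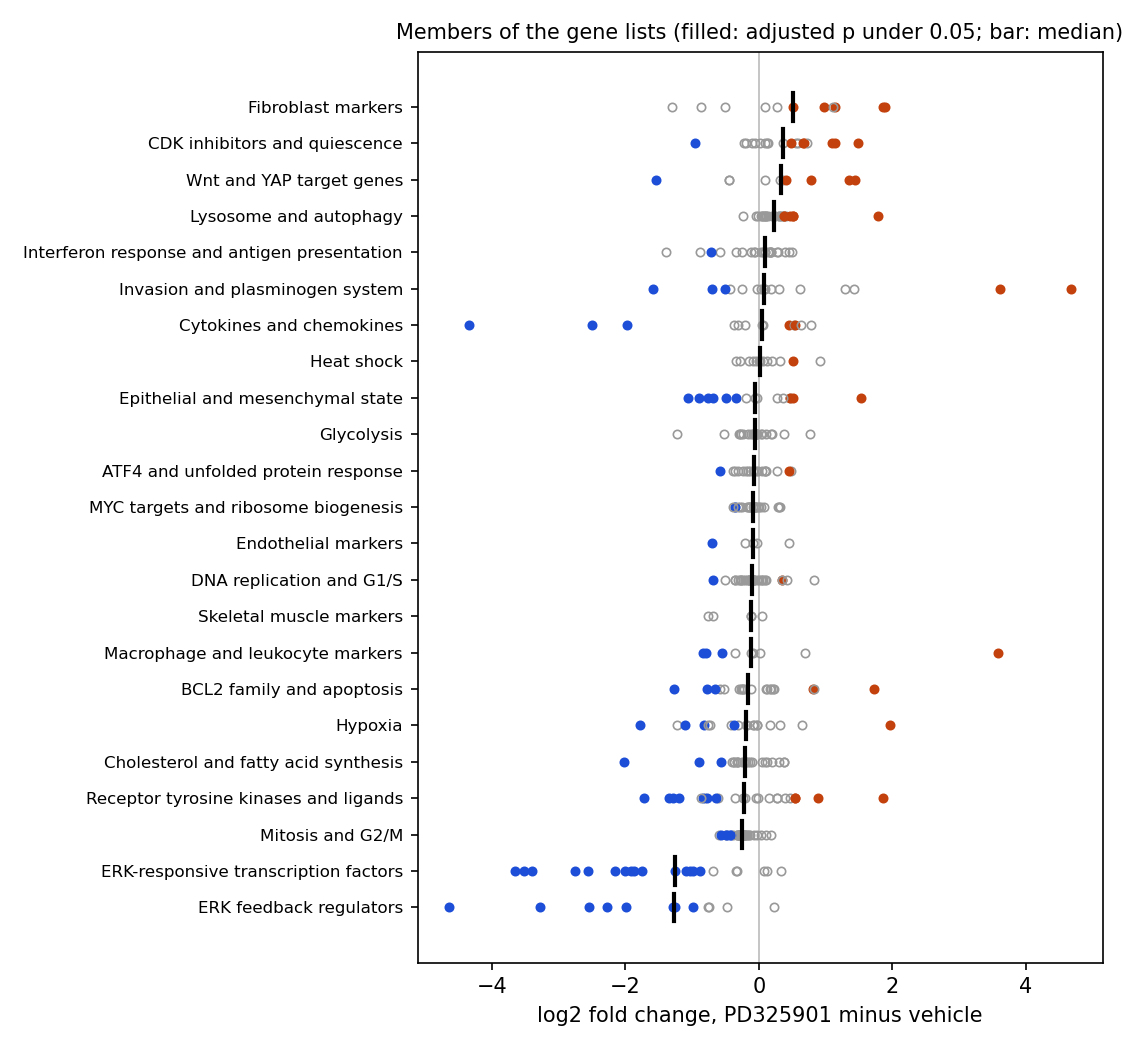
Log2 fold change, PD325901 minus vehicle, of each measured member of the 23 lists with at least 5 measured members. Filled points passed an adjusted p of 0.05, open points did not, and the black bar is the list's median. The 2 ERK-linked lists have the lowest medians, -1.28 and -1.26, and most other medians lie near 0.

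Lists of markers of other cells differed in their change between the groups. Human probes can take up mouse RNA, so these lists describe cells the samples could hold. Of 11 measured fibroblast markers, 5 rose, none fell and 6 did not pass (6 rose and 1 fell when adjusted over the list alone). FAP, the fibroblast activation protein gene, was 3.71-fold higher (adjusted p = 0.00225), while DCN, chosen after its values were seen, had a log2 fold change of -1.30 (adjusted p = 0.247). With normexp the log2 fold change of FAP was 1.14, against 1.89 in the main comparison. The list passed camera with the preset correlation (adjusted p = 0.0426), not with an estimated correlation (adjusted p = 0.334), and it passed in 12 of 22 alternatives (adjusted p from 0.0122 to 0.231). Its score was 0.47 higher with overlapping groups (exact permutation p = 0.114), at 0.47 and 0.67 in PD325901 replicates 3 and 4, where acinar transcripts were high, and at -0.25 in replicate 1, below vehicle replicates 2 and 4 (-0.09 and -0.10). ACTA2, COL1A2 and COL5A1 also rose and are named after their values were seen, as are FCER1G and TYROBP below. Of 5 endothelial markers 1 fell, PLVAP (-0.70, adjusted p = 0.0415), likewise over the list alone (camera adjusted p = 0.726), a call kept in 5 of 21 alternatives (adjusted p from 0.0121 to 0.198). Of 9 macrophage and leukocyte markers, CSF1R rose and 3 fell, CD14 (-0.84, adjusted p = 0.0338), FCER1G and TYROBP, likewise over the list alone. The call of CD14 was kept in 14 of 22 alternatives (adjusted p from 0.0180 to 0.0850). That list had a median log2 fold change of -0.12, a mean of 0.17 and a camera adjusted p of 0.641. None of 5 skeletal muscle markers passed (limma; 0 had an unadjusted p under 0.05; camera adjusted p = 0.526), TNNI2 having a log2 fold change of -0.69 and TNNT3 of -0.77. None of 4 erythroid markers passed (limma; 1 had an unadjusted p under 0.05), HBD having a log2 fold change of -1.40 (adjusted p = 0.0720) and HBA2 of -1.06. In 1 of 22 alternatives each, TNNI2 (adjusted p from 0.0235 to 0.426) and HBD (from 0.0350 to 0.290) passed. Of 2 adipocyte markers, CIDEC rose (0.40, adjusted p = 0.0140), with -0.33 under normexp (adjusted p = 0.372, the highest of a range that starts at 0.00370). Lists with under 5 measured members had no camera test.

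Of 3 measured pancreatic acinar markers 1 rose, the trypsinogen gene PRSS2, and 1 fell, the colipase gene CLPS (-0.59, adjusted p = 0.0380), whose call was kept in 10 of 22 alternatives (adjusted p from 0.0307 to 0.114). Over the list alone 2 rose and 1 fell. PRSS2 went from 0.53 ± 3.12 to 6.35 ± 2.65 (SD, n = 4 per group; limma, adjusted p = 0.0495), with overlapping groups and a log2 fold change of 0.30 on its second kept probe, and its call was kept in 8 of 22 alternatives (adjusted p from 0.0181 to 0.317). With single tumours left out its log2 fold change ran from 4.93 (without vehicle replicate 1) to 7.29 (without vehicle replicate 2). Among genes chosen after their values were seen, the elastase gene CELA2A stood at 7.52 and 8.33 in PD325901 replicates 3 and 4, at 3.19 in vehicle replicate 2 and at -3.17 in vehicle replicate 1.

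**Figure D3:**
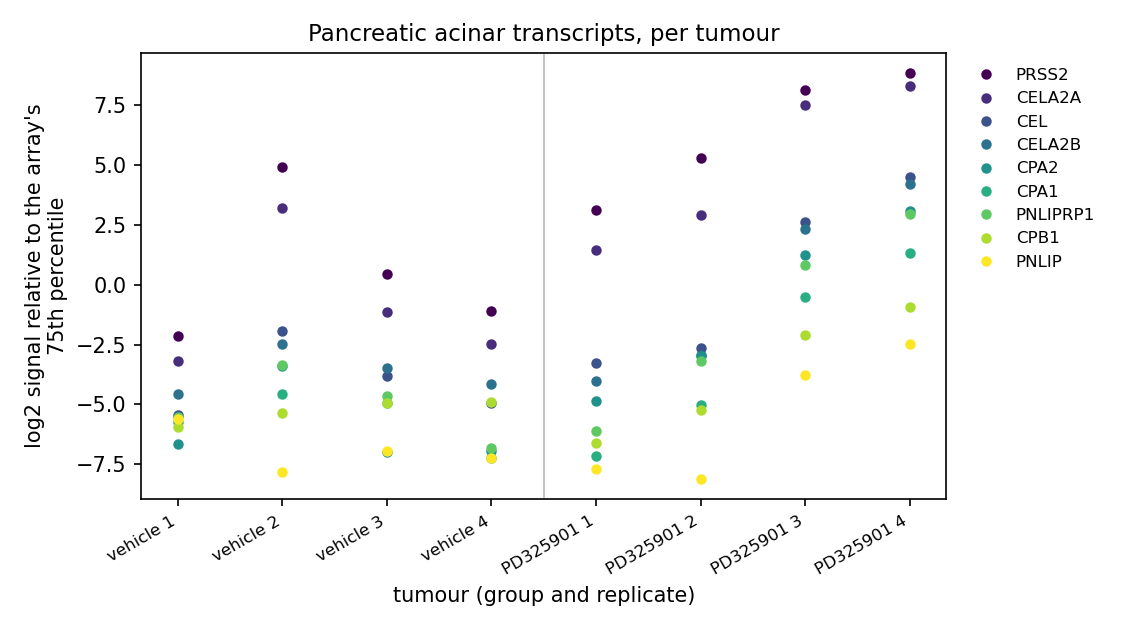
Log2 signal relative to the 75th percentile of each array for 9 acinar transcripts, drawn after their values were seen, one point per tumour, with vehicle tumours on the left and PD325901 tumours on the right of the grey line. Each of the 9 is highest in PD325901 replicate 4, where PRSS2 reaches 8.85 and CELA2A 8.33.

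Kinases of the pathway named for context did not pass. The log2 fold change was -0.18 ± 0.18 (SE) for MAP2K1 and 0.29 ± 0.13 (SE) for MAP2K2, which encode MEK1 and MEK2, and 0.28 ± 0.18 (SE) for MAPK3, which encodes an ERK kinase. Their adjusted p (limma) was 0.546, 0.154 and 0.319.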

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

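Apart from the counts over splits of the tumours, the tests in this part, those of the slides, the acinar transcripts and the fibroblast markers, were chosen after the result was seen.

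The difference between the groups exceeds what other groupings of these tumours give. Of the 35 splits of the 8 tumours into 4 and 4, only the real one (1 of 35) called 1890 genes, 888 of them higher and 1002 lower, 464 at least 2-fold, or 3152 probes, and the highest of the other splits called 0 of each at the adjusted threshold (limma). At an unadjusted p under 0.05 the real split gave 3931 genes and the highest other 1213. Ranking first of 35 splits is the strongest result this design allows, so chance is unlikely but not excluded for these counts. The other splits mix the groups, which widens their spread, so a count of 0 there was likely in advance. The real split is also the split by slide. The count of lists called by camera with the preset correlation did not stand out: 14 of the 35 splits called at least 6 lists, and the highest other split called 15.

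The fall of the ERK-linked lists was weighed against the slides. A labelling or hybridisation difference that acts on all probes of like brightness is argued against for probes above background. The largest difference between the slides among spike-in RNAs above background and 10 equal groups of probes by brightness was 0.280 log2 units in size. The list medians were -1.28 and -1.26. Every spike-in RNA above background was lower on the PD325901 slide, by log2 differences from -0.193 to -0.280 (PD325901 minus vehicle). A change as small as the median of -0.25 of the mitosis list is therefore not set apart from the slides by these values. Array scaling limits how far the medians of the probe groups can differ, so these groups alone would be a weak test. Spike-ins left out because not all their spots were flagged as well above background differed by -0.73, -0.77, -0.44 and -0.14 log2 units (PD325901 minus vehicle). The last of these was bright, with a mean of 6.06 under vehicle and 5.92 under PD325901, so only the others describe dim probes. For probes near background under PD325901, such as those of EGR3 and DUSP6, the value of 0.280 therefore sets no limit. A difference between the slides that acts on single probes stays open, because 0 slides hold both treatments, so it cannot be told apart from treatment. A response of the tumours to the MEK inhibitor may explain these falls and stays open beside it.

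Acinar transcripts varied between tumours, also on probes outside the comparison. The probes for CPA1, CPB1, PNLIP and PRSS1 were left out of the test because no group had them well above background on all of its arrays. They were so on 3, 3, 2 and 2 PD325901 arrays in that order and on 1, 1, 0 and 1 vehicle arrays, and their highest PD325901 value exceeded the highest vehicle value by 5.90, 3.96, 3.13 and 0.97 log2 units. Acinar cells in differing shares in the tumours are a candidate source: 15 further acinar genes, from a list written before the test, had a median Spearman correlation of 0.38 with the profile of the 7 detected acinar list genes over the 8 tumours, which 0.4% of 10000 random sets of detected probes reached, a test that replaced an earlier count on those 15 genes that had picked tumours by their values. Of the 15, 6 had correlations above 0.7, such as CELA2A (0.952), 3 lay between 0 and 0.7, and 6 were negative, among them the acinar regulators RBPJL (-0.738) and BHLHA15 (-0.405), while CTRB1 was not well above background in any tumour. The RBPJL probe was well above background on 1 vehicle array and 0 PD325901 arrays, so its correlation rests mostly on values near background. A direct rise under PD325901 stays open, with a mean profile 2.22 log2 units higher and an exact permutation p of 0.2.

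Of 11 fibroblast markers 5 rose, while 1 of 5 endothelial markers fell, and of 9 macrophage and leukocyte markers 1 rose and 3 fell. A lower share of tumour cells, which would raise all host cells alike, could not be decided on. The fibroblast score minus the mean of the other 2 scores was 0.44 log2 units higher under PD325901 (exact permutation p = 0.0286, the smallest the design allows), apart in 4 of 4 tumours. However, this contrast was chosen after the fibroblast list was seen to rise. Among PD325901 tumours the fibroblast, endothelial and macrophage scores also moved together. They were -0.25, -0.39 and -0.39 in replicate 1 and 0.67, 0.15 and 0.48 in replicate 4. More fibroblasts of the same kind may be present, and the count of falling markers could not decide, with 1 of 11 markers lower by over 2 standard errors. A change within the fibroblasts, or expression of these genes by the tumour cells, was not tested and stays open.

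Single tumours stood far from the other 3 of their group in 11 of 170 groups tested, where chance gives about 1 in 20. The value is the gap to the nearest tumour over the range of the group. Vehicle replicate 3 was apart for LY6D (0.884, highest), EGR4 (0.854, highest), GAS1 (0.885, highest), CCN2 (0.847, lowest) and MAPK3 (0.919, lowest). PD325901 replicate 1 was highest for TOX2 (0.866), replicate 4 lowest for PTTG1 (0.887) and replicate 3 highest for CCN2 (0.831). Among list scores, vehicle replicate 2 was highest for CDK inhibitors and quiescence (0.895) and lowest for MYC targets and ribosome biogenesis (0.8295), and vehicle replicate 1 was highest for endothelial markers (0.886).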

How the results depend on the processing

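The settings that leave out PD325901 replicates 3 and 4 together and vehicle replicates 1 and 3 together were chosen after the result was seen, and the other alternatives were planned. The fall of both ERK-linked lists passed camera with the preset correlation in all 22 alternatives to the processing, samples and variance model (adjusted p from 2.13e-13 to 1.99e-06 and from 5.82e-17 to 1.32e-09), but not with an estimated correlation (adjusted p = 0.0911 and 0.104). Of 53 named genes past the threshold, 23 passed under each alternative that tested them and 51 held their direction, PDGFRB and CIDEC being the exceptions. Unless stated otherwise, the cause of the differences below was not tested. The slide block was not run, since each slide held 1 treatment. Genes not well above background on any array of a group have only a bound on their fold.

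With normexp, 1152 genes changed (456 higher, 309 at least 2-fold), with 938 of them among the 1890, and 1615 probes. It called 3 lists, and the adjusted p of mitosis was 0.101. Camera turned upward for glycolysis (0.482), interferon (0.580), MYC targets and ATF4 (both 0.913). Scores were 0.015 for interferon and -0.090 for macrophages, and log2 fold changes were -0.27 for PDGFRB and -0.33 for CIDEC. Quantile normalization turned camera upward for glycolysis and endothelial markers (both 0.937), with scores of 0.0014 for BCL2, 0.058 for epithelial and mesenchymal state, 0.019 for glycolysis and 0.10 for endothelial markers. Median scaling moved the median of all genes to 0.16 and called 1789 genes higher and 636 lower. Camera turned downward for invasion (0.803), and scores became positive: DNA replication 0.075, BCL2 0.11 (exact permutation p = 0.0286), epithelial and mesenchymal state 0.092, glycolysis 0.083, interferon 0.085, MYC targets 0.066, ATF4 0.099 and endothelial markers 0.039. Cyclic loess turned camera upward for endothelial markers (0.939), with scores of 0.031 for epithelial and mesenchymal state and 0.075 for endothelial markers.

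Without a filter on detection 535 genes were higher and 1680 probes changed, among more genes tested. Camera turned upward for glycolysis and interferon (both 0.708) and ATF4 (0.993), and the macrophage score was -0.18. With probes well above background on all 8 arrays camera turned downward for invasion (0.8293). With the replicate block, although the replicate numbers do not pair the tumours (0 of 4 correlations above 0.1), 1083 genes changed, 459 higher and 624 lower, and 1938 probes, and camera turned upward for interferon (0.99902). Array quality weights turned it upward for interferon (0.917). With an estimated correlation 0 lists passed, and the adjusted p was 0.725 for mitosis. With fry the adjusted p was 0.169 for mitosis, and macrophage markers turned upward (0.567). The other lists that camera called passed with fry. Their adjusted p was 3.41e-05 for ERK feedback regulators, 0.000304 for ERK-responsive transcription factors, 0.000389 for lysosome, 0.0131 for CDK inhibitors and quiescence and 0.00603 for fibroblast markers. At an unadjusted p under 0.05, 3931 genes differed.

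Leaving out single tumours gave 962 to 1839 changed genes (436 to 941 higher, 526 to 988 lower) and 1485 to 3032 changed probes, with fewer samples. The count was over 1.5 times lower without PD325901 replicates 3 (962), 1 (1093) or 2 (1209) or vehicle replicate 2 (1229), and 544 genes were higher without PD325901 replicate 4. Camera reversed in at least 1 such case for invasion (adjusted p from 0.574 to 0.951), glycolysis (0.301 to 0.969), interferon (0.384 to 0.951), heat shock (0.384 to 0.952), endothelial markers (0.538 to 0.963) and macrophages (0.465 to 0.951), none of which passed. Scores ranged from -0.13 to 0.0059 for DNA replication, -0.15 to 0.00031 for BCL2, -0.12 to 0.016 for glycolysis and -0.17 to 0.040 for interferon. Without PD325901 replicates 3 and 4 together 642 genes changed, 231 higher and 411 lower, and 653 probes, and camera turned upward for hypoxia (0.938) and glycolysis (0.373). Without vehicle replicates 1 and 3 together 1295 genes changed, 641 of them lower, 3 lists passed and ATF4 turned upward (0.913).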

Other observations

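The Hedgehog test in this part was chosen after the result was seen for its member GAS1, the other 2 tests were written before their members' values had been examined, and all 3 were prompted by genes of the main comparison. Genes named here were chosen after their values were seen.

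LY6D and KRT6A, genes of stratified epithelium, rose, and TRIM29, a gene of basal epithelium, was at least 6.08-fold higher on its brightest probe, which was not well above background on any vehicle array, with a log2 fold change of 0.78 on its second kept probe. The hypothesis that genes of stratified epithelium rise together was tested on 18 other measured genes. Of these, KRT16, KRT17 and KLK5 rose and KRT15, KRT4 and S100A2 fell, with a median log2 fold change of -0.09. The set as a whole did not pass (camera adjusted p = 0.732 over the 3 lists tested in this part). Since its members moved both ways, the test cannot decide whether some of these genes rose together. KRT16 was 4.77-fold higher and KRT17 3.11-fold higher, from 0.48 ± 0.28 to 2.74 ± 0.34 and from -3.01 ± 0.29 to -1.37 ± 0.42 (SD, n = 4 per group; limma, adjusted p = 0.000318 and 0.00268), while S100A2 was 3.04-fold lower. The keratins of simple epithelium KRT8 and KRT18, which stand in the list of epithelial and mesenchymal state, fell, with log2 fold changes of -0.76 and -0.69.

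GLI1, the transcription factor and target of Hedgehog signalling, was 8.06-fold higher, from -3.49 ± 0.16 to -0.48 ± 0.45 (SD, n = 4 per group; limma, adjusted p = 0.000161). Of 9 other Hedgehog target and receptor genes measured, CDON and GAS1 rose (log2 fold changes of 1.04 and 1.48) and SFRP1 fell (-0.71), while PTCH1 had a log2 fold change of -0.26. The test that these genes rise together did not pass (median log2 fold change 0.01, camera adjusted p = 0.480). Since the set mixes targets with receptors and other pathway genes, it cannot decide whether Hedgehog targets alone moved.

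The complement regulator CFI also fell, with a log2 fold change of -2.58, beside CFHR3. Of 11 other complement genes measured, CD59 rose (0.41) and CD46 fell (-0.73). The test that complement genes fall together did not pass, with a median log2 fold change of 0.30 (camera adjusted p = 0.467).

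Median log2 fold changes depended on brightness, from -0.25 in the dimmest of 10 equal groups of kept probes to 0.04 in group 6 and -0.05 in the brightest.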
